A study of Mus musculus with 24 samples.

How the data were processed

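RNA of 24 mouse samples was extracted with Trizol, fragmented, labelled with biotin and hybridised to Affymetrix mouse gene arrays, 1 array per sample. The values used are the deposited table of log2 expression per probe set, made with RMA in the R package oligo per the submitters' processing notes, whose versions are not given in the sources used here. RMA corrects background, normalizes arrays by quantiles and summarises probes. Whether all 24 arrays were normalized together is not stated, and scanner files were not used here. The table held 35556 probe sets with values from 3.80 to 14.31, 0 of them non-finite. Correlations between arrays over all probe sets lay between 0.906 and 0.995, and 0 pairs of arrays were identical (the closest pair differed by a root mean square of 0.155).

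Probe sets were named from the platform annotation: 21789 had 1 gene symbol, 1621 several and 12146 none, and only those with 1 were used. Gene identifiers of 21698 probe sets matched the RefSeq gene table of assembly GRCm38.p6, which was used for symbols alone. Of 19938 genes, 999 had more than 1 probe set, and the one with the highest mean over all arrays stood for the gene. No dim genes were left out and no minimum fold was set. Samples were grouped by their titles, which call the replicates biological. The sources give no hybridisation dates or batches.

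Groups were compared on the deposited log2 values with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, two-sided, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05). The 14 arrays of the leukaemia set shared 1 estimate of the spread, as did the 10 arrays of the precursor set, and differences between stages were tested on all 24. In the text, changes are log2 changes ± SE from that fit. Gene lists, 29 of pathways and gene programmes and 12 of cell type markers, 41 in all, had 780 of 859 members measured. Each list was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 41 lists. At the preset correlation 25, 31, 16, 19, 15 and 12 lists passed in the 6 comparisons in the order of the report, and with an estimated correlation 0 passed in each (8, 12, 8, 3, 3 and 2 at an unadjusted p under 0.05), so no list call holds with an estimated correlation. Fry, which asks whether a list's genes move one way and does not set them against other genes, passed 24, 27, 6, 1, 13 and 0.

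Genes were named by a rule: in each comparison Pax5, Abl1 and Bcr; the 6 largest rises and 6 largest falls among genes past the test whose arrays do not overlap between groups, leaving out antigen receptor segments and unnamed gene models; and, of each list described, up to 3 members past the test with the smallest adjusted p, or the 1 with the smallest p where none passed. For differences between stages, 4 up and 4 down were named without the overlap condition. The grouping, tests, lists, naming rule and most alternatives were fixed before the data were examined. Which lists were described with their members was chosen after their values were seen. Beside a list's count over all genes stands the count adjusted over the list alone.

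The fit was tested on simulated data, with known log2 changes of 0.5, 1 and 2 put into 67, 67 and 66 of the 19938 genes. At these sizes it recovered 61.2, 89.6 and 100% in heterozygous leukaemias against B220+ cells, 37.3, 70.1 and 95.5% in leukaemias with both copies against B220+ cells and 49.3, 74.6 and 98.5% between the leukaemias. For heterozygous precursors against wild type it recovered 50.7, 95.5 and 97%, for precursors with both copies against wild type 52.2, 94 and 97% and between the oncogene-bearing precursors 46.3, 91 and 97%. For differences between stages the shares were 20.9, 71.6 and 86.4% for the Pax5 copy, 32.8, 82.1 and 89.4% for the heterozygous groups and 25.4, 65.7 and 87.9% for the groups with both copies. False calls, in the same order, were 8 of 175, 11 of 146 and 7 of 155 called genes in the leukaemia set. They were 12 of 174, 8 of 170 and 11 of 167 for precursors, and 11 of 130, 14 of 150 and 6 of 125 for stages. The simulated noise was independent between genes, with 1 spread per gene in all groups. Real groups differ in spread, so these shares may not hold for the real arrays.

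Replicate numbers recur across groups. Deviations from the group means correlated between same-numbered oncogene-bearing precursors (heterozygous and with both copies) in all 3 pairs, from 0.208 to 0.25, over the limit of 0.1 set for pairing. The pairing comes from the data, since the labels name no shared litter or day. Arrays with unlike numbers reached higher values, as did precursor 1 with both copies and wild-type precursor 2 (0.441). The pairing is therefore not established. Other groups share numbers alone. Alternatives were other scalings (quantile, median centring, cyclic loess), array weights, a spread that follows intensity, a dim filter, the mean of all probe sets or every probe set, a minimum fold, other sets of arrays in the fit, the other wild-type group as control, sex and the first residual component as covariates, the replicate block, and each array left out. Comparisons that share controls were set against 100 simulations of unchanged groups, for the precursors also with their pairing. A surrogate-variable fit was planned and not run.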

Results

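Gene expression was measured on 24 Affymetrix mouse gene arrays, 1 array per mouse sample, in 6 groups that fall into a leukaemia set and a precursor set. The leukaemia set held tumour-bearing bone marrow of 7 mice that carried the BCR/ABLp190 fusion oncogene under the Sca1 promoter and were heterozygous for Pax5 (heterozygous leukaemias), bone marrow of 2 mice with the same oncogene and both Pax5 copies (leukaemias with both copies), and B220+ marrow B cells of 5 wild-type mice. The precursor set held pro-B and pre-B cells of mice without leukaemia: 3 samples with the oncogene and heterozygous Pax5 (heterozygous precursors), 3 with the oncogene and both copies (BCR/ABL precursors with both copies) and 4 from wild-type mice. The series description counts 3 wild-type precursor mice, while the sample labels give 4, and all 4 were used. Pax5 encodes a transcription factor that sets and keeps B cell identity, and the study asked how its dosage and the oncogene bear on metabolism in the development of precursor B cell leukaemia. The number of arrays limits the precision. The first principal component held 46.6% of the variance and placed all 9 leukaemias apart from the other 15 arrays. By Xist and Y-linked genes, all 9 wild-type arrays came from females, all 3 BCR/ABL precursors with both copies from males, and the other groups were mixed.

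Pax5 was read first, on every array. In the heterozygous leukaemias its log2 level was 8.45, 10.43, 9.93, 10.95, 8.37, 10.30 and 12.06 on arrays 1 to 7 (10.07 ± 1.32, mean ± SD, n = 7), and in the leukaemias with both copies 8.10 and 8.39 (8.24 ± 0.21, n = 2). The B220+ cells had 12.24, 12.44, 12.42, 12.20 and 12.33 (12.33 ± 0.11, n = 5). The heterozygous precursors had 11.80, 11.58 and 12.00 (11.79 ± 0.21, n = 3), the BCR/ABL precursors with both copies 11.93, 12.03 and 12.19 (12.05 ± 0.13, n = 3) and the wild-type precursors 11.86, 11.81, 11.93 and 12.02 (11.91 ± 0.093, n = 4). Where the probe set lies relative to the disrupted part of the allele is not given in the sources used here, so the level does not check the labels. In the heterozygous leukaemias Pax5 fell against B220+ cells by 2.26 ± 0.53 on the log2 scale (SE), adjusted p = 0.0063, with all 7 arrays below the B220+ mean, and in the leukaemias with both copies it fell by 4.09 ± 0.76, adjusted p = 0.00241. The B lineage markers, Pax5 included, had a median of -2.27 in the heterozygous leukaemias. The labels name no sort for leukaemic marrow, so a lower share of B lineage cells cannot be told apart from less Pax5 per cell. The difference of 1.83 ± 0.73 between the leukaemias did not pass the test (adjusted p = 0.263), nor did those of the heterozygous precursors against wild type (-0.11 ± 0.10, adjusted p = 0.543), of the precursors with both copies against wild type (0.14 ± 0.10, adjusted p = 0.312), or between the oncogene-bearing precursors (-0.25 ± 0.11, adjusted p = 0.345). The mouse genes Abl1 and Bcr passed limma in no comparison except Bcr in the heterozygous leukaemias against B220+ cells (-0.56 ± 0.18, adjusted p = 0.0295). Abl1 there had 0.23 ± 0.18, adjusted p = 0.322. Whether their probe sets match the human transgene is not known, so these levels are no reading of the oncogene. The Bcr call was lost without any 1 of heterozygous leukaemias 1, 2, 4 and 7 (adjusted p = 0.0502, 0.0524, 0.0522 and 0.0506) or of B220+ arrays 2, 3 and 5 (0.062, 0.0576 and 0.0707). Without array 1 of the leukaemias with both copies, Abl1 in that group reached 0.61 against B220+ cells, from -0.041, and passed (adjusted p = 0.0429).

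**Figure D1:**
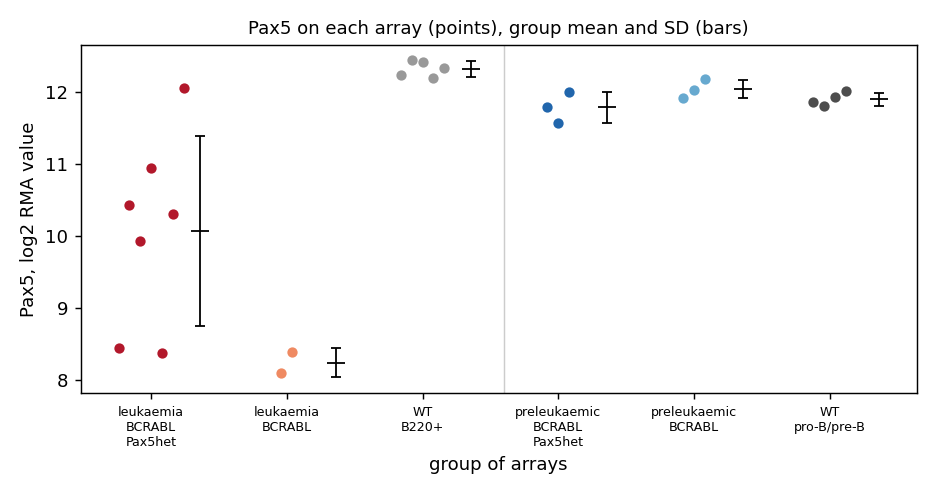
Pax5 log2 expression on each of the 24 arrays (vertical axis, log2) by group (horizontal axis), with points for arrays and bars for the group mean ± SD. The heterozygous leukaemias spread from 8.37 to 12.06, while the 5 arrays of B220+ cells lie between 12.20 and 12.44.

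The first comparison asked how marrow with heterozygous leukaemia (n = 7) differed from B220+ marrow cells of wild-type mice (n = 5). Kcnma1, a calcium-activated potassium channel, rose most among named genes, from 6.49 ± 0.26 to 13.53 ± 0.29 (mean ± SD), a log2 change of 7.05 ± 0.27 (SE) or 132-fold (adjusted p = 5.67e-09). Serpinb9d (5.40 ± 0.67), the antibody joining chain Jchain (5.06 ± 0.41), the matrix genes Sparc (4.92 ± 0.36) and Bgn (4.73 ± 0.41) and the chemokine Cxcl9 (4.80 ± 0.80) rose as well. Genes of B cells fell: Ms4a1, which encodes CD20 (-5.43 ± 0.58), Fcmr, an IgM receptor (-5.43 ± 0.41), and Cd72 (-4.30 ± 0.76). Cpm (-5.28 ± 0.27), the fatty acid desaturase Scd1 (-4.56 ± 0.59) and Klhl14 (-4.34 ± 0.10) fell as well. Of 22 measured PAX5-activated genes 21 fell and 0 rose, with a median of -2.75, among them Cr2 (-4.09 ± 0.25), Ikzf3 (-4.05 ± 0.25) and Id3 (-2.16 ± 0.16); the list passed (camera adjusted p = 7e-12, and adjusted p = 0.164 with an estimated correlation). Of 11 B lineage markers 10 fell, among them Cd79b (-1.41 ± 0.21) and Cd22 (-1.87 ± 0.30). The B lineage list had a median of -2.27 (camera adjusted p = 6.01e-05, and adjusted p = 0.189 with an estimated correlation). The counts were the same for both lists when adjusted over the list alone. Of 22 antibody and T cell receptor segments, 1 rose and 8 fell. In later comparisons 1 rose and 1 fell in leukaemias with both copies, 1 rose in heterozygous precursors and 5 rose in precursors with both copies. The labels name no sort for leukaemic marrow, and markers of other marrow cells moved with these genes. Of 18 monocyte and macrophage markers 15 rose (17 adjusted over the list alone), among them Csf1r (3.75 ± 0.41), Mrc1 (4.16 ± 0.56) and Vcam1 (4.42 ± 0.61). The monocyte and macrophage list had a median of 2.94 (camera adjusted p = 6.87e-10, and adjusted p = 0.189 with an estimated correlation). Of 14 stroma and endothelium markers 12 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 2.22 (camera adjusted p = 2.15e-08, and adjusted p = 0.189 with an estimated correlation). Of 9 megakaryocyte markers 8 rose (9 adjusted over the list alone), with a median of 1.91 (camera adjusted p = 2.03e-05, and adjusted p = 0.282 with an estimated correlation).

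Of 35 cell cycle genes 31 rose in the same comparison (32 adjusted over the list alone), among them the spindle checkpoint kinase Bub1b (1.44 ± 0.15), Cenpf (1.65 ± 0.17) and the replication helicase subunit Mcm3 (1.00 ± 0.11). The cell cycle list had a median of 0.95 (camera adjusted p = 4.81e-19, and adjusted p = 0.189 with an estimated correlation). This direction holds against B220+ cells only: against wild-type precursors Bub1b had -0.70, Cenpf -0.31 and Mcm3 -0.11, the list had a median of -0.38, and Cr2 had 0.10. With that control 8 of the 45 named genes lost the call or turned, the MYC target median was 0.38 and that of oxidative phosphorylation 0.018, and the energy control list passed (median 0.24, camera adjusted p = 0.0177). Camera at an estimated correlation was not run with that control. Of 31 MYC target genes 21 rose (26 adjusted over the list alone), with Ncl (0.84 ± 0.11) and Nop58 (1.17 ± 0.16) of ribosome assembly among them. The MYC target list had a median of 0.63 (camera adjusted p = 6.8e-13, and adjusted p = 0.189 with an estimated correlation). Of 21 glycolysis genes 8 rose and 2 fell (9 and 2 adjusted over the list alone). The glycolysis list had a median of 0.28 (camera adjusted p = 0.000607, and adjusted p = 0.189 with an estimated correlation). Lactate dehydrogenase Ldha (0.92 ± 0.10), Pgk1 (0.92 ± 0.14) and Pdk1 (1.48 ± 0.19), which restrains entry of pyruvate into mitochondria, were among those that rose. Of 57 oxidative phosphorylation genes 16 rose and 1 fell (16 and 1 adjusted over the list alone), with complex I subunits Ndufc2 (0.86 ± 0.11) and Ndufv2 (0.55 ± 0.077) higher and Ndufs8 (-0.69 ± 0.11) lower. The oxidative phosphorylation list had a median of 0.17 (camera adjusted p = 1.64e-05, and adjusted p = 0.293 with an estimated correlation). Of 15 genes through which PAX5 and IKZF1 are known to limit energy supply, 6 rose and 3 fell (6 and 3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.176, and adjusted p = 0.282 with an estimated correlation). The list was defined without a direction for each member, so a test for a shift one way cannot decide whether this control changed. The glucose handling genes Hk2 (0.85 ± 0.16) and Slc2a3 (1.32 ± 0.26) rose, and the cannabinoid receptor Cnr2 (-3.03 ± 0.23) fell. In nucleotide synthesis 14 of 19 genes rose and 1 fell (15 and 1 adjusted over the list alone). The nucleotide synthesis list had a median of 0.77 (camera adjusted p = 3.35e-08, and adjusted p = 0.189 with an estimated correlation).

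By limma with Benjamini-Hochberg adjustment, 6336 of 19938 genes changed between heterozygous leukaemias and B220+ cells, 2569 higher and 3767 lower (40.5% higher). With a log2 change of at least 1 the balance turned, with 959 higher and 559 lower. All 45 named genes past the test had every leukaemia array on the side of the change. The naming rule favours this, here and in each later comparison, so it does not measure how alike the arrays are. Of all 6336 called genes, 3820 had no overlap between the groups. The share of higher genes depended on the scaling: 16.4% of 12413 genes after median centring and 53.1% after cyclic loess. Median centring moved the median change of all genes from -0.060 to -0.20, and the lists named above kept the sign of their medians under each scaling.

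The leukaemias with both Pax5 copies (n = 2) were compared with the same B220+ cells to ask how marrow with the oncogene and both gene copies differed. The labels name no sort for this marrow, so the comparison cannot tell an effect of the oncogene from a difference in cell types. Pax5 expression itself was lower here (-4.09). Kcnma1 rose here too (6.02 ± 0.39, adjusted p = 1.62e-06), as did Sparc (4.75 ± 0.51). Neutrophil granule genes rose: Ctsg (5.67 ± 0.68), Mpo (5.03 ± 0.84) and Prtn3 (4.71 ± 0.46), with the platelet gene Ppbp (4.91 ± 0.79). Of 22 neutrophil and granulocyte precursor markers 14 rose (22 adjusted over the list alone), Fcnb (3.09 ± 0.35) among them. The neutrophil list had a median of 3.33 (camera adjusted p = 1.25e-13, and adjusted p = 0.18 with an estimated correlation). Erythroid markers had a median of 2.42 with 0 of 13 members past limma (camera adjusted p = 0.000116, and adjusted p = 0.339 with an estimated correlation). It rests on array 1 of the leukaemias (array means of 11.81 and 7.52): without it the erythroid median was 0.31 (camera adjusted p = 0.434), and without array 2 4.41. Of 18 monocyte and macrophage markers 9 rose (13 adjusted over the list alone), with a median of 2.40 (camera adjusted p = 1.69e-07, and adjusted p = 0.18 with an estimated correlation), or 1.54 without array 1. Of 22 PAX5-activated genes 21 fell (the same count adjusted over the list alone), among them Ikzf3 (-4.43 ± 0.36), Irf4 (-4.10 ± 0.47) and Cr2 (-3.87 ± 0.36). The PAX5-activated list had a median of -3.48 (camera adjusted p = 1.63e-13, and adjusted p = 0.0943 with an estimated correlation). Cpm (-6.33 ± 0.39), Vpreb3 (-5.56 ± 1.20), Ms4a1 (-5.19 ± 0.83), Fcer2a, which encodes CD23 (-5.01 ± 1.10), Niban3 (-4.74 ± 0.70) and Cd72 (-4.58 ± 1.09) fell. With wild-type precursors as the control, Fcer2a had 0.48 and Cr2 0.31, the opposite sign. Of 17 genes of antigen receptor signalling 12 fell (13 adjusted over the list alone), among them the kinases Syk (-1.91 ± 0.17) and Btk (-0.95 ± 0.10) and the Ras activator Rasgrp1 (-3.82 ± 0.40). The receptor signalling list had a median of -1.16 (camera adjusted p = 2.17e-07, and adjusted p = 0.0944 with an estimated correlation).

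Among cell cycle genes 33 of 35 rose in leukaemias with both copies (34 adjusted over the list alone), including Cenpf (2.17 ± 0.25), Mcm3 (1.32 ± 0.16) and Kif20a (1.94 ± 0.25). The cell cycle list had a median of 1.46 (camera adjusted p = 1.36e-26, and adjusted p = 0.0944 with an estimated correlation). With wild-type precursors as the control it was 0.21 (camera adjusted p = 0.0452), Cenpf had 0.20, Mcm3 0.21 and Kif20a 0.23, none of these 3 genes past the test, and 7 of the 29 named genes lost the call or turned. Of 21 glycolysis genes 11 rose and 1 fell (14 and 2 adjusted over the list alone), with Pfkm (1.67 ± 0.22), Pkm (0.74 ± 0.12) and Ldha (0.87 ± 0.14) higher. The glycolysis list had a median of 0.74 (camera adjusted p = 7.66e-07, and adjusted p = 0.0943 with an estimated correlation). Of 20 antioxidant genes 11 rose (13 adjusted over the list alone), with Gsr (2.94 ± 0.44), Txnrd1 (0.89 ± 0.13) and mitochondrial superoxide dismutase Sod2 (0.67 ± 0.12) among them. The antioxidant list had a median of 0.68 (camera adjusted p = 1.29e-07, and adjusted p = 0.0943 with an estimated correlation). Without array 1 of the leukaemias the glycolysis median was 1.13 and the antioxidant median 0.28. By limma 4260 genes changed, 1891 higher and 2369 lower (44.4% higher; 19.1% of 8809 after median centring and 55.8% after cyclic loess). With a log2 change of at least 1 the balance turned, with 1042 higher and 724 lower. The count rests on array 1 of the leukaemias: 2235 genes changed without it and 4755 without array 2, with the lone array assumed to vary like the other groups, and with array weights it was 2281. All 29 named genes past the test had both leukaemia arrays on the side of the change, and 2 of them lost the call without array 1.

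Fold changes of the leukaemia comparisons ran together across genes, which are not independent replicates. Both set marrow whose labels name no sort against B220+ cells, and what this adds to the correlation was not tested. Pearson's r was 0.794 and Spearman's rho 0.763, where unchanged groups simulated against the same controls gave r = 0.405. The covariance was 0.362 against 0.0214 in the simulation, and with separate subsets of the controls r lay between 0.723 and 0.806. Genes higher in both numbered 1279, where independent lists of those sizes share 244; 1909 were lower in both against 448, and 17 moved in opposite directions against 663.

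The third comparison set the leukaemias against each other and asked what Pax5 heterozygosity changed in overt disease (n = 7 against 2). Heterozygous leukaemias had higher Serpinb9d (5.32 ± 0.92), the NK receptor gene Klri1 (4.34 ± 0.88), the RNA-binding protein gene Igf2bp3 (3.41 ± 0.35), Myl4 (3.35 ± 0.77), the interleukin-2 receptor chain Il2ra (3.21 ± 0.53) and Plch1 (2.93 ± 0.41). Neutrophil granule genes were lower: Ctsg (-4.78 ± 0.65), Chil3 (-4.44 ± 0.87), Mpo (-4.13 ± 0.81), Prtn3 (-3.98 ± 0.44) and Camp (-3.96 ± 0.74). Mc5r differed by -4.03 ± 0.74, with a level of 9.62 ± 3.26 on the arrays with both copies (-6.33 without array 1 of these and -1.73 without array 2). Of 22 neutrophil and granulocyte precursor markers 11 were lower (21 adjusted over the list alone), with Fcnb (-3.44 ± 0.33) and the granulocyte factor Cebpe (-2.49 ± 0.28) among them. The neutrophil list had a median of -3.42 (camera adjusted p = 2.78e-26, and adjusted p = 0.231 with an estimated correlation). The list averaged 8.07 ± 0.90 (mean ± SD) in heterozygous leukaemias and 11.39 ± 0.49 in those with both copies. Erythroid markers had a median of -1.41 with 0 of 13 past limma (camera adjusted p = 0.003, and adjusted p = 0.704 with an estimated correlation), and averaged 8.30 ± 1.37 in heterozygous leukaemias. The leukaemias with both copies had array means of 11.81 and 7.52, and without array 1 the erythroid median was 0.88, the opposite sign (camera adjusted p = 0.0659; -3.29 without array 2). Of 17 NF-kB target genes 4 were higher (10 higher and 1 lower adjusted over the list alone), among them Icam1 (1.02 ± 0.19), Birc3 (1.06 ± 0.23) and Nfkbia (1.14 ± 0.26). The NF-kB list had a median of 0.92 (camera adjusted p = 2.97e-07, and adjusted p = 0.231 with an estimated correlation). Of 23 immature and mature B cell genes 2 were higher, the BAFF receptor Tnfrsf13c (2.10 ± 0.39) and Cd37 (1.00 ± 0.19), or 7 adjusted over the list alone. The mature B cell list had a median of 1.00 (camera adjusted p = 1.61e-06, and adjusted p = 0.249 with an estimated correlation).

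In metabolism, 4 of 21 glycolysis genes were lower in heterozygous leukaemias, the same count adjusted over the list alone, with Hk3 (-1.98 ± 0.38), Pfkm (-0.95 ± 0.21) and Ldhb (-1.75 ± 0.39) among them. Pfkm no longer passed without array 1 of the leukaemias with both copies (-0.45, adjusted p = 0.488; -1.45 without array 2), nor Ldhb without array 2 (-0.80, adjusted p = 0.189; -2.70 without array 1). The glycolysis list had a median of -0.29 (camera adjusted p = 0.00102, and adjusted p = 0.249 with an estimated correlation). Without array 2 of the leukaemias with both copies that median was 0.029, the opposite sign, and the pentose phosphate list no longer passed (camera adjusted p = 0.0972); without array 1 the medians were -0.45 and -0.47. Of 9 pentose phosphate genes 2 were lower, Pgd (-0.85 ± 0.17) and Rpia (-1.06 ± 0.23), or 4 adjusted over the list alone; without array 1 Rpia had -0.56 (adjusted p = 0.464), and -1.56 without array 2. The pentose phosphate list had a median of -0.31 (camera adjusted p = 0.00145, and adjusted p = 0.213 with an estimated correlation). Neutrophil markers were lower in the same comparison (median -3.42), but the 2 list medians did not follow them by array. Array 1 with both copies had the higher neutrophil mean (11.73, and 11.04 on array 2), while the glycolysis median was 0.029 without array 2. Pfkm and Rpia, in contrast, differed more on array 1. Of 15 energy control genes 1 was higher, the mTOR inhibitor gene Ddit4 (2.86 ± 0.49), and 1 lower (4 and 3 adjusted over the list alone). The list had a median of -0.16 and a mean of 0.093 and did not pass (camera adjusted p = 0.948, and adjusted p = 0.943 with an estimated correlation). For a list defined without a direction this decides nothing. All 25 named genes past the test had all 7 heterozygous arrays on the side of the change, as the naming rule favours. By limma 373 genes differed, 142 higher and 231 lower. The count was 2137 without array 2 of the leukaemias with both copies, 85 from those groups alone and 83 with array weights. Of the 25 named genes 17 and 2 lost the call without array 1 or 2 of that group, and 6, 5, 4, 4, 4, 2 and 2 without heterozygous leukaemia 1 to 7 in turn. From those groups alone 18 lost it, as did 18 with array weights.

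**Figure D2:**
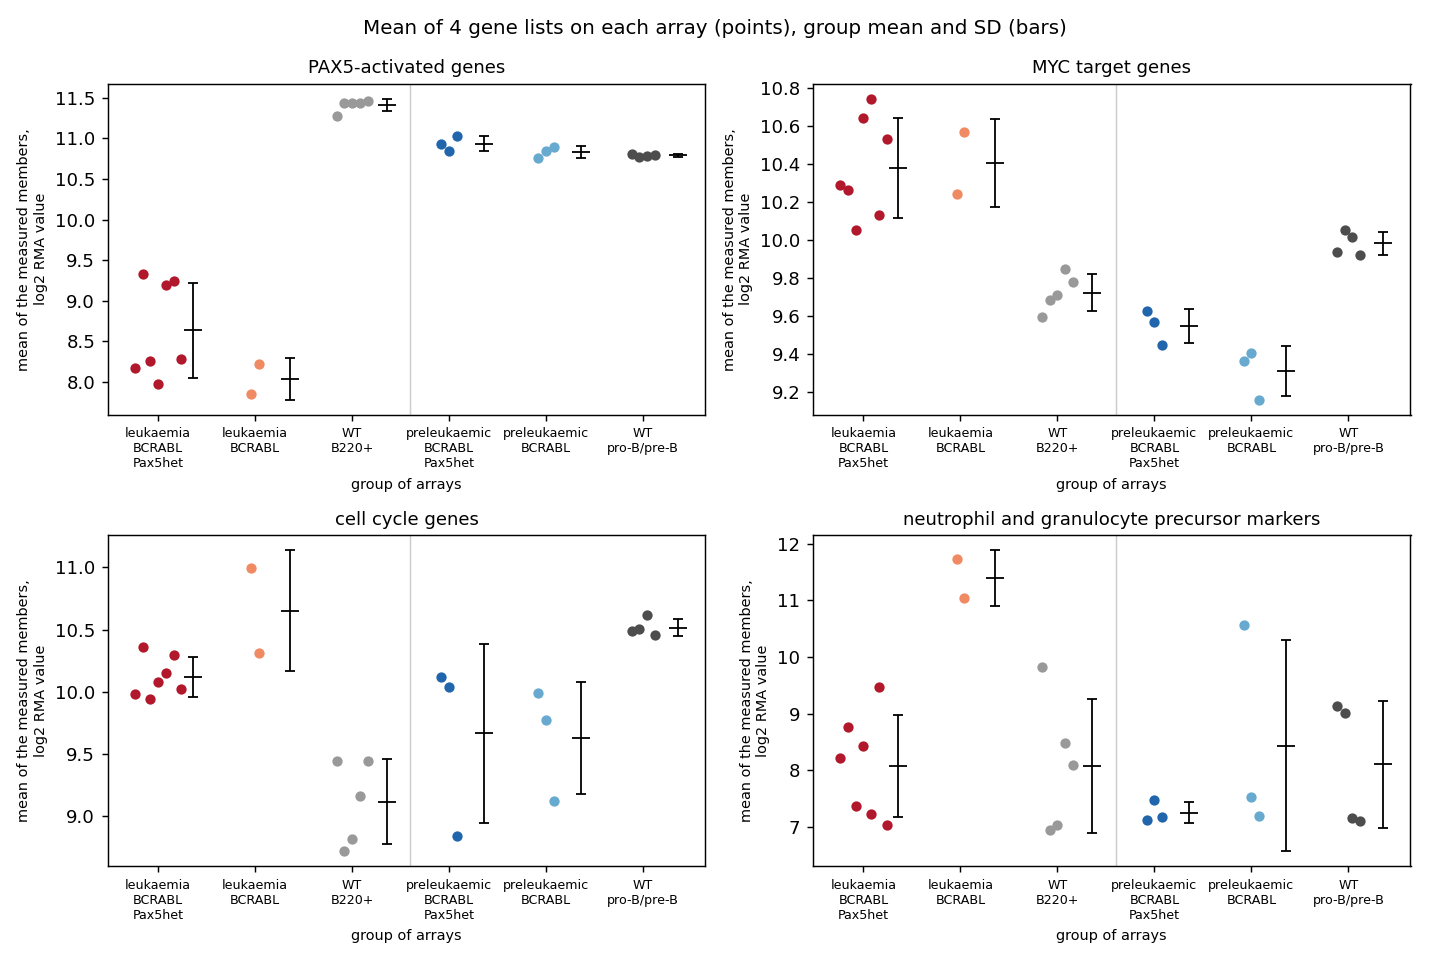
Mean log2 expression per array (vertical axis, log2) of the PAX5-activated, MYC target, cell cycle and neutrophil lists, 1 panel each, by group (horizontal axis), with points for arrays and bars for the group mean ± SD. PAX5-activated genes averaged 8.64 ± 0.59 in heterozygous leukaemias and 11.41 ± 0.078 in B220+ cells, and both leukaemias with both copies lie above the heterozygous ones in the neutrophil list.

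In the precursor set, heterozygous precursors (n = 3) were compared with wild-type precursors (n = 4) to ask what oncogene and Pax5 heterozygosity changed before leukaemia. Smoc1 (1.46 ± 0.13), the endolysosomal channel Mcoln2 (1.29 ± 0.24), the interferon-induced Rtp4 (1.24 ± 0.14), Nav2 (1.09 ± 0.093), Unc5a (1.09 ± 0.19) and Tnfrsf19 (1.06 ± 0.15) rose. Enpep, the BP-1 antigen of early B cells (-2.79 ± 0.25), Emb (-2.67 ± 0.52), the chemokine receptor Ccr2 (-2.21 ± 0.34), Cd300c (-1.84 ± 0.44) and Prelid2 (-1.80 ± 0.37) fell, as did the NK receptor Ncr1 (-1.90 ± 0.35). Of 12 NK cell markers 4 fell (10 adjusted over the list alone), Klrk1 (-1.36 ± 0.28) and Klrb1c (-1.28 ± 0.29) among them. The NK cell list had a median of -1.19 (camera adjusted p = 1.24e-07, and adjusted p = 0.42 with an estimated correlation). The list averaged 7.61 ± 0.53 in heterozygous and 8.74 ± 0.34 in wild-type precursors; plasmacytoid dendritic cell markers had a median of -0.80 (-0.53 without heterozygous array 3), erythroid -0.82 and neutrophil -0.88 (-0.49 and -0.58 without wild-type array 1 or 2). The plasmacytoid and neutrophil lists no longer passed without heterozygous array 3 (camera adjusted p = 0.155 and 0.135), nor did the neutrophil list without wild-type array 1 or 2 (0.119 and 0.115). With an estimated correlation none of the 41 lists passed in this comparison (lowest camera adjusted p = 0.42). Against B220+ cells Klrk1 had 0.038, Klrb1c 0.20, Fcer2a -4.92 and Spib -0.065, each the opposite sign; the NK median was 0.060 and the PAX5-activated median -0.054, the interferon list no longer passed (0.0041, camera adjusted p = 0.439), and 26 of the 30 named genes lost the call or turned. Of 22 PAX5-activated genes 3 rose and 0 fell (4 rose adjusted over the list alone): Id3 (0.83 ± 0.14), Fcer2a (0.57 ± 0.12) and Spib (0.28 ± 0.060). The PAX5-activated list had a median of 0.13 (camera adjusted p = 0.0152, and adjusted p = 0.43 with an estimated correlation). Of 27 interferon response genes 8 rose and 1 fell (10 and 2 adjusted over the list alone), including Oas2 (1.02 ± 0.15) and Oasl1 (1.05 ± 0.16). The interferon list had a median of 0.26 (camera adjusted p = 0.00486, and adjusted p = 0.43 with an estimated correlation). Without heterozygous array 3 the PAX5-activated list no longer passed (median 0.063, camera adjusted p = 0.166); without heterozygous array 2 its median was 0.26, and 0.34 with sex in the fit. The interferon median was 0.17, 0.40 and 0.11 without heterozygous array 1, 2 or 3.

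Of 31 MYC target genes 9 fell in heterozygous precursors (24 adjusted over the list alone), with Rcl1 (-0.46 ± 0.060) and the chaperonin Hspd1 (-1.21 ± 0.21) among them. The MYC target list had a median of -0.36 (camera adjusted p = 5.74e-15, and adjusted p = 0.42 with an estimated correlation), beside a median of -1.19 for NK cell markers. Of 19 nucleotide synthesis genes 4 fell (12 adjusted over the list alone), the pyrimidine genes Umps (-0.80 ± 0.12), Cad (-0.53 ± 0.12) and Ctps (-0.93 ± 0.21) among them. The nucleotide synthesis list had a median of -0.53 (camera adjusted p = 2.08e-08, and adjusted p = 0.42 with an estimated correlation). Of 24 cholesterol and fatty acid synthesis genes 6 fell (10 adjusted over the list alone), with Cyp51 (-0.79 ± 0.11), Hmgcs1 (-0.68 ± 0.11) and Idi1 (-1.20 ± 0.20). The cholesterol and fatty acid synthesis list had a median of -0.26 (camera adjusted p = 3e-06, and adjusted p = 0.42 with an estimated correlation). In glycolysis 3 of 21 fell, the same count adjusted over the list alone: Ldha (-0.88 ± 0.13), Ldhb (-0.43 ± 0.077) and Pfkp (-0.53 ± 0.12). The glycolysis list had a median of -0.13 (camera adjusted p = 0.0152, and adjusted p = 0.42 with an estimated correlation), and without heterozygous array 3 it no longer passed (median -0.077, camera adjusted p = 0.143). Nor did it pass after quantile normalization (-0.063, camera adjusted p = 0.102), cyclic loess (0.0922), array weights (0.0515) or the dim filter (0.151), or against B220+ cells (0.151), where the nucleotide synthesis list did not pass either (-0.013, camera adjusted p = 0.607) and the MYC target and cholesterol medians were -0.18 and -0.15. The nucleotide synthesis median was -0.34 with array weights and -0.82 with sex in the fit, the cholesterol median -0.15 after quantile normalization and -0.41 with sex in the fit, and the glycolysis median -0.045 without the arrays high in neutrophil markers. All 30 named genes past the test had all 3 heterozygous arrays on the side of the change, as the naming rule favours. With a log2 change of at least 1, 10 genes were higher and 82 lower. By limma without a minimum fold 832 genes changed, 245 higher and 587 lower (29.4% higher, and 52.8% after quantile normalization). The count rests on single arrays: it was 115, 75, 37 and 508 without wild-type array 1, 2, 3 or 4, 431 without heterozygous array 1 and 397 without array 2. Without wild-type arrays 1 and 2 and array 1 of the precursors with both copies, whose neutrophil marker means were over 9, limma gave 0 genes, with 2479 at an unadjusted p under 0.05, and all 30 named genes lost the call. Leaving out wild-type array 1, 2, 3 or 4 ended 18, 24, 26 and 8 of those calls, and leaving out heterozygous array 1, 2 or 3 ended 11, 10 and 5. With sex in the fit (2 of the 3 heterozygous arrays were male by Xist and all 4 wild-type arrays female) limma gave 1139 genes, 327 of them among the 832, and 10 of the 30 named genes lost the call. With all 24 arrays in 1 fit the count was 275 and 22 of the 30 lost it.

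BCR/ABL precursors with both copies (n = 3) were compared with the same wild-type precursors (n = 4) to ask what the oncogene alone changed. Sex-linked genes differed, with the arrays of this group all male and the wild-type arrays all female by Xist: Eif2s3y (4.96 ± 0.99), Kdm5d (3.05 ± 0.64) and Uty (2.99 ± 0.62) were higher and Xist (-6.18 ± 1.33) lower. With sex in the fit Kdm5d had -0.045 and Xist 0.40. The interferon-induced Ifi27l2a (1.38 ± 0.34), Gfod1 (1.19 ± 0.22) and Uchl1 (1.19 ± 0.27) rose. Ctse (-3.02 ± 0.40), the glutamine transporter Slc1a5 (-2.42 ± 0.47) and Cacna2d1 (-2.21 ± 0.47) fell. The NK genes Ncr1 (-2.69 ± 0.35) and granzyme Gzma (-2.15 ± 0.40) fell as well, and of 12 NK cell markers 10 fell (11 adjusted over the list alone), Klrb1c (-1.59 ± 0.29) and Klrk1 (-1.56 ± 0.28) among them. The NK cell list had a median of -1.58 (camera adjusted p = 1.44e-06, and adjusted p = 0.56 with an estimated correlation). Of 8 plasmacytoid dendritic cell markers 4 fell (5 adjusted over the list alone), with a median of -0.89 (camera adjusted p = 0.0174, and adjusted p = 0.611 with an estimated correlation), and without array 1 of the group the list no longer passed (camera adjusted p = 0.151). The NK median was -2.70 with sex in the fit, and against B220+ cells it was -0.22 and did not pass (camera adjusted p = 0.441).

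Of 31 MYC target genes 29 fell in these precursors (30 adjusted over the list alone), with Polr1b of RNA polymerase I (-0.94 ± 0.086), Rcl1 (-0.65 ± 0.060) and Mybbp1a (-0.94 ± 0.094). The MYC target list had a median of -0.61 (camera adjusted p = 1.12e-15, and adjusted p = 0.391 with an estimated correlation), beside a median of -1.58 for NK cell markers. Of 35 cell cycle genes 17 fell (25 adjusted over the list alone), with Cdc25c (-1.34 ± 0.29), Mcm4 (-0.68 ± 0.15) and Bub1b (-1.62 ± 0.40); against B220+ cells these had 0.44, 0.19 and 0.52. The cell cycle list had a median of -0.79 (camera adjusted p = 7.26e-08, and adjusted p = 0.611 with an estimated correlation), -2.20 with sex in the fit and 0.50 against B220+ cells. Of 25 citric acid cycle genes 15 fell (17 with 1 higher adjusted over the list alone), with Idh3a (-1.28 ± 0.17), Suclg2 (-0.89 ± 0.16) and Sucla2 (-0.81 ± 0.15). The citric acid cycle list had a median of -0.28 (camera adjusted p = 9.9e-07, and adjusted p = 0.391 with an estimated correlation). Of 18 fatty acid oxidation genes 9 fell (11 with 1 higher adjusted over the list alone), with Hadhb (-0.62 ± 0.061), Echs1 (-0.92 ± 0.10) and Acadm (-0.80 ± 0.11). The fatty acid oxidation list had a median of -0.34 (camera adjusted p = 0.000308, and adjusted p = 0.391 with an estimated correlation). Of 24 cholesterol and fatty acid synthesis genes 15 fell and 1 rose (17 and 1 adjusted over the list alone), with Hmgcs1 (-0.99 ± 0.11), Cyp51 (-0.91 ± 0.11) and Fdft1 (-1.20 ± 0.16). The cholesterol and fatty acid synthesis list had a median of -0.60 (camera adjusted p = 4.16e-07, and adjusted p = 0.391 with an estimated correlation). Of 21 glycolysis genes 7 fell (9 adjusted over the list alone), with Ldha (-1.09 ± 0.13), Pfkp (-0.78 ± 0.12) and Pdk1 (-0.83 ± 0.15). The glycolysis list had a median of -0.20 (camera adjusted p = 0.0142, and adjusted p = 0.391 with an estimated correlation). It did not pass after quantile normalization (-0.11, camera adjusted p = 0.143), cyclic loess (0.171) or the dim filter (0.239), or against B220+ cells (-0.092, camera adjusted p = 0.198), where the cholesterol median was -0.37. After quantile normalization and cyclic loess the fatty acid oxidation list did not pass either (-0.13 and -0.14, camera adjusted p = 0.211 and 0.12), and the citric acid cycle median was -0.061 and -0.084, or -0.16 with sex in the fit. With all genes ranked into 5 bins from dim to bright, bins 1 to 3 had medians of 0.075, 0.14 and 0.11 in this comparison. Bins 4 and 5 had -0.23 and -0.20. Whether these lists moved beyond genes of like brightness was not tested.

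By limma 5396 genes changed in the precursors with both copies, 2314 higher and 3082 lower (42.9% higher; 54.2% after quantile normalization and 31.6% after median centring). With a log2 change of at least 1 there were 15 higher and 272 lower. Most changes were small, with a median size of 0.40 on the log2 scale. All 32 named genes past the test had all 3 arrays on the side of the change, as the naming rule favours. Values spread less on these arrays, with an SD over genes of 1.85 against 1.97 in wild-type precursors. The count was 3390 and 2331 without array 2 or 3 of the group, and 3196, 2973 and 2722 without wild-type array 1, 2 or 3. It was 3536 after cyclic loess, 983 with sex in the fit and 243 without the 3 precursor arrays high in neutrophil markers. Of the 32 named genes 19 lost the call or turned with sex in the fit, 15 with B220+ cells as control and 23 without those 3 arrays, and 1, 3 and 1 did without array 2 or 3 of the group or wild-type array 3.

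The precursors with the oncogene were compared with each other (n = 3 against 3) to ask what Pax5 heterozygosity changed before leukaemia. By limma 5 genes differed: Smoc1 (1.24 ± 0.14, adjusted p = 0.0272), Synpo2 (1.07 ± 0.11, adjusted p = 0.0257) and Rassf2 (0.56 ± 0.065, adjusted p = 0.0284) were higher in the heterozygous precursors, and Edaradd (-1.40 ± 0.14, adjusted p = 0.0237) and the histone deacetylase Hdac11 (-0.87 ± 0.074, adjusted p = 0.0105) lower, each on all 3 arrays. No member of the lists described here passed limma over all genes. MYC target genes had a median of 0.22 (5 of 31 higher adjusted over the list alone; camera adjusted p = 1.17e-07, and adjusted p = 0.666 with an estimated correlation), with Polr1b at 0.49 ± 0.092 (adjusted p = 0.144). Fatty acid oxidation genes had a median of 0.15 (6 of 18 higher adjusted over the list alone; camera adjusted p = 7.55e-05, and adjusted p = 0.666 with an estimated correlation), with Hadhb at 0.32 ± 0.066 (adjusted p = 0.149). Glycolysis genes had a median of 0.066 (-0.0077 after quantile normalization and -0.0099 after cyclic loess), 0 members past limma adjusted over the list alone, and a list test that did not pass (camera adjusted p = 0.248, and adjusted p = 0.666 with an estimated correlation); Pdk1 had 0.66 ± 0.16 (adjusted p = 0.172). PAX5-activated genes had a median of 0.037 (-0.033 after cyclic loess; 3 of 22 higher adjusted over the list alone; camera adjusted p = 0.18, and adjusted p = 0.666 with an estimated correlation), with Fcer2a at 0.56 ± 0.13 (adjusted p = 0.161). Neutrophil markers had a median of -1.20 and erythroid markers -0.73; without array 1 of the precursors with both copies these were -0.13 (camera adjusted p = 0.572) and -0.25, and without array 3 the neutrophil median was -1.996. The fatty acid oxidation list did not pass after quantile normalization (0.031, camera adjusted p = 0.122) or cyclic loess (0.029, 0.132), where the MYC target median was 0.13 and 0.10. Without array 3 of the precursors with both copies the MYC target median was 0.14, and without array 1 that of fatty acid oxidation was 0.23. With all genes ranked into 5 bins from dim to bright, bins 1 to 3 had medians of -0.027, -0.066 and -0.059 here. Bins 4 and 5 had 0.15 and 0.14. Whether these lists differed beyond genes of like brightness was not tested. At an unadjusted p under 0.05 limma gave 2849 genes. With the replicate number as a block limma gave 0 genes (2687 unadjusted), as it did from those groups alone (1813) and without the arrays high in neutrophil markers (2592). The count was 1, 138 and 16 without heterozygous array 1, 2 or 3 and 3 and 1 without array 1 or 2 of the other group. Of the 5 genes 4 lost the call without heterozygous array 1 and 3, 4 and 1 without array 1, 2 or 3 of the other group.

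Fold changes of the precursor comparisons against wild type also ran together across genes (Pearson's r = 0.803, Spearman's rho 0.759; 0.428 for unchanged groups simulated against the same controls). The covariance was 0.0742 against 0.00909 simulated, and separate subsets of the controls gave r between 0.634 and 0.786. That simulation treats the oncogene-bearing groups as independent; with same-numbered arrays deviating together at their mean correlation of 0.224, unchanged groups gave r = 0.556 and a covariance of 0.0118. Genes higher in both numbered 138 against 28.4 for independent lists, 542 were lower in both against 90.7, and 1 moved in opposite directions against 106. All wild-type arrays were female and most of the others male, and what sex adds to the correlation was not tested.

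**Figure D3:**
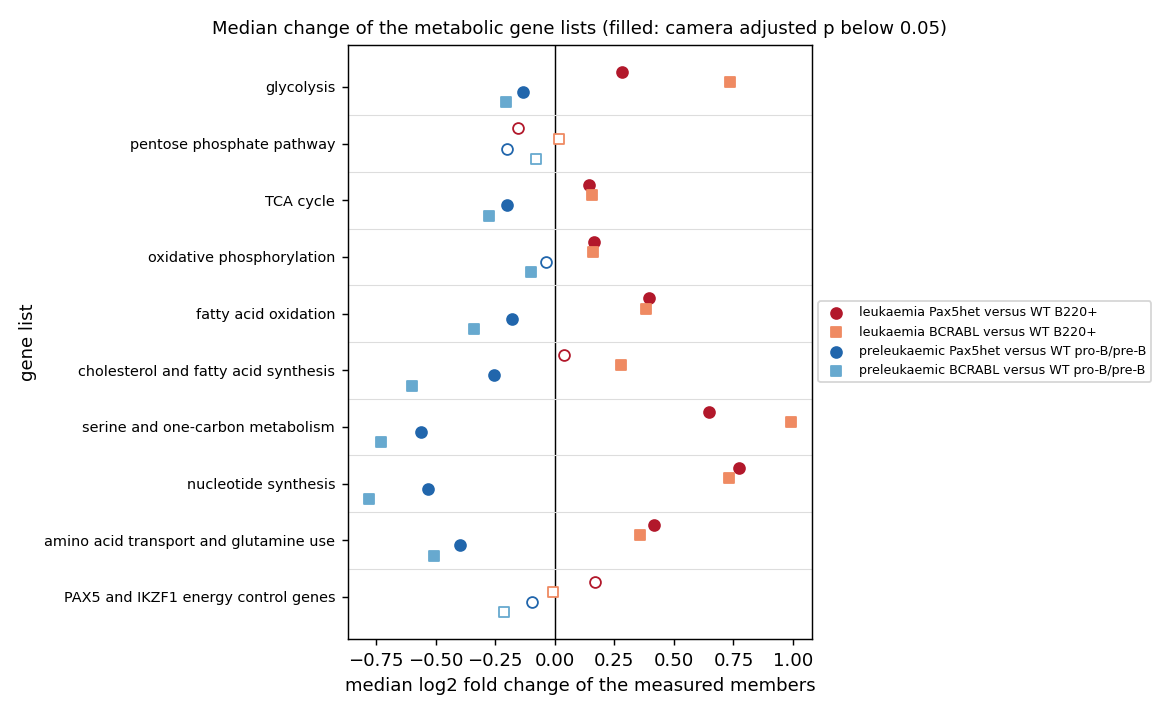
Median log2 fold change (horizontal axis, log2) of 10 metabolic gene lists (vertical axis) in the 4 comparisons against wild type, with circles for heterozygous and squares for groups with both copies, red and orange for leukaemias, blue for precursors, and filled symbols where camera's adjusted p was below 0.05. Nucleotide synthesis lies at 0.77 and 0.73 in the leukaemias and -0.53 and -0.78 in the precursors; under another scaling the sign turns for cholesterol synthesis in heterozygous leukaemias, for pentose phosphate and energy control genes in leukaemias with both copies, for oxidative phosphorylation in both precursors and for pentose phosphate genes in precursors with both copies.

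Whether an effect differed between leukaemia and precursor stages was tested on all 24 arrays as a difference of comparisons. The controls differ between the stages (B220+ cells and precursors), and the labels name no sort for the leukaemias. Across genes, fold changes against wild type at the 2 stages had Pearson's r = -0.292 in the heterozygous groups. There 331 called genes moved in opposite directions (122 for independent lists), 14 were higher in both and 59 lower in both. With both copies r was -0.152, with 893 opposite (567 for independent lists), 87 higher in both and 194 lower in both. For the Pax5 copy r was 0.278. For the heterozygous groups against wild type 6016 genes differed, 2471 in the direction of a higher value in leukaemia and 3545 lower, while 1361 upward and 663 downward differences were of at least 1 on the log2 scale. Kcnma1 (7.55 ± 1.98), Jchain (7.18 ± 0.77), Serpinb9d (5.38 ± 0.88) and Rnase12 (5.30 ± 1.20) had the largest positive differences and Fcmr (-5.95 ± 0.57), Cpm (-5.59 ± 0.39), Ms4a1 (-4.73 ± 0.80) and Adck1 (-4.56 ± 1.20) the largest negative ones. Of 31 MYC target genes 26 differed upwards (27 adjusted over the list alone), as did 33 of 35 cell cycle genes (33 adjusted over the list alone). The cell cycle list had a median of 1.70 (camera adjusted p = 1.9e-21, and adjusted p = 0.128 with an estimated correlation). This holds the difference between the controls, whose cell cycle mean was 9.12 in B220+ cells and 10.49, 10.50, 10.61 and 10.46 on the wild-type precursor arrays. Heterozygous leukaemias averaged 10.12, and the heterozygous precursor arrays had 10.12, 10.04 and 8.84. For MYC target genes the controls lay closer, at 9.73 and from 9.92 to 10.05. The MYC target list had a median of 1.14 (camera adjusted p = 4.03e-17, and adjusted p = 0.113 with an estimated correlation). For the groups with both copies 7463 genes differed, 3009 upwards and 4454 downwards, or 1807 upwards and 720 downwards at a size of at least 1. Kcnma1 (8.51 ± 2.33), Emb (5.33 ± 0.71), Jchain (5.31 ± 0.91) and Ctse (5.31 ± 1.00) led upwards and Cpm (-6.32 ± 0.46), Vpreb3 (-5.67 ± 1.30), Fcer2a (-5.01 ± 1.20) and Niban3 (-4.93 ± 0.77) downwards. MYC target genes (26 of 31, 28 adjusted over the list alone) and cell cycle genes (35 of 35, 35 adjusted over the list alone) differed upwards here too. The cell cycle list had a median of 2.19 (camera adjusted p = 8.36e-23, and adjusted p = 0.102 with an estimated correlation). The MYC target list had a median of 1.32 (camera adjusted p = 3.47e-16, and adjusted p = 0.0984 with an estimated correlation). The share of upward differences moved with the scaling, from 41.1% to 18.1% of 11138 after median centring and 53.6% after cyclic loess in the heterozygous groups, and from 40.3% to 26.6% and 52.3% in the others. Without B220+ array 1, wild-type precursors 1 and 2 and precursor 1 with both copies, whose neutrophil marker means were over 9, the counts were 2994 and 4269.

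The effect of the Pax5 copy itself differed between the stages in 138 genes, 45 upwards and 93 downwards in leukaemia (32.6% upwards; 50.3% after cyclic loess, 45.4% after quantile normalization and 19.7% after median centring). Serpinb9d (5.36 ± 1.05, adjusted p = 0.0172), Igf2bp3 (3.08 ± 0.41), Plch1 (3.01 ± 0.48) and Il2ra (2.88 ± 0.62) differed upwards, and Mc5r (-3.98 ± 0.85; -6.28 and -1.67 without leukaemia 1 or 2 with both copies) and the neutrophil genes Prtn3 (-3.60 ± 0.64), Ms4a3 (-3.01 ± 0.57) and Padi4 (-2.88 ± 0.50) downwards. Of 22 neutrophil and granulocyte precursor markers 4 differed downwards (8 adjusted over the list alone). The neutrophil list had a median of -2.07 (camera adjusted p = 2.46e-09, and adjusted p = 0.478 with an estimated correlation), or -3.25 and -1.37 without precursor 1 or 3 with both copies. NF-kB target genes had a median of 0.70, with 0 of 17 past limma over all genes and 6 higher adjusted over the list alone (camera adjusted p = 2.98e-06, and adjusted p = 0.315 with an estimated correlation). The count was 301 and 1381 without leukaemia 1 or 2 with both copies, 211 and 222 without heterozygous leukaemia 5 or 6, 80 without heterozygous precursor 1, 52 and 59 without precursor 2 or 3 with both copies, and 38 with array weights. Of the 8 named genes 4 and 4 lost the call without precursor 2 or 3 with both copies, and 2, 2 and 1 without heterozygous precursor 1, 2 or 3. With array weights 4 lost it, and 3 did without the arrays high in neutrophil markers.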

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

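The tests of the explanations for lower B cell genes in leukaemia and for neutrophil genes were chosen after the result was seen, as was the comparison of folds and SE in the precursors with both copies. The other tests for the precursors and the splits of the arrays were written before their results. The sex covariate was chosen after the data were seen, and its bounds were written with the sexes of the arrays known.

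B lineage and PAX5-activated genes were lower in leukaemic marrow than in B220+ cells, with medians of -2.27 and -2.75 in the heterozygous leukaemias. The B lineage markers fell by unlike amounts, and 4 of 11 lay more than 2 SE from the list median: Cd79b -1.41, Cd72 -4.30, Ms4a1 -5.43 and Ptprc -0.23, which other leukocytes also express. Unlike falls cannot exclude a lower share of B lineage cells, since markers can differ in their expression by other cells and in signal over background. Mature B cells in the control are not the whole cause, since with wild-type precursors as control the PAX5-activated median was -2.31, though Cr2 turned sign there. Loss of 1 Pax5 copy is not the whole cause, since the median was -3.48 with both copies and 0.49 in heterozygous against both-copy leukaemias (camera adjusted p = 0.00848, and adjusted p = 0.485 with an estimated correlation; SD over members 0.63; 0 members past limma); that list no longer passed without array 1 or 2 with both copies (median 0.38 and 1.02, camera adjusted p = 0.0538 and 0.0837). Combinations of these were not tested, and whether Pax5 dosage adds anything is open.

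Precursors with both copies showed 5396 changed genes of small size against wild type, and their arrays had the narrowest range of values. The direction ran with brightness. With genes ranked into 5 bins from dim to bright, 278 rose and 30 fell in bin 1, and 816 and 119 in bin 2. In bin 3 846 rose and 560 fell, in bin 4 212 and 1268, and in bin 5 162 and 1105. The medians of all genes per bin were 0.075, 0.14, 0.11, -0.23 and -0.20. A narrower range would give this direction, which does not exclude another cause. After quantile normalization 2610 of the 5396 passed as well. The median log2 change of the 5396 in its original direction was 0.30 ± 0.30 (SD over genes), from 0.40 ± 0.29, with a median SE of 0.089, from 0.094. Of these changes 1072 grew, and why calls ended was not tested. With sex in the fit 574 of the 5396 passed, with a median change of 0.31 ± 0.47 and a median SE of 0.17. Of these changes 2080 grew, and the NK and cell cycle medians went from -1.58 and -0.79 to -2.70 and -2.20. Neither a narrower range nor sex can be told apart from the oncogene by these values: the shares that passed lie between the bounds set beforehand, all 3 mice of the group were male and all wild-type mice female, and the sex term rests on 1 array, heterozygous precursor 3, the female of its group. The oncogene remains open beside both.

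Neutrophil and granulocyte precursor genes were higher in leukaemias with both copies than in heterozygous ones. A single array is not the cause, since the lower of the 2 arrays with both copies lay 1.57 above the highest heterozygous array in the list mean. A lower share of leukaemic cells would raise the markers of other cell types too, though not necessarily by the same amount. In heterozygous against both-copy leukaemias the neutrophil median was -3.42 and that of monocyte and macrophage markers 0.38 (SD over members 0.985). The latter turned with the array left out, but stayed apart from the neutrophil list: without array 2 with both copies the monocyte, megakaryocyte, stroma, erythroid and neutrophil medians were -0.62, -1.06, -0.59, -3.29 and -3.80, and without array 1 1.26, 0.62, 0.66, 0.88 and -2.97. With 2 arrays, and all these medians negative without array 2, a lower share of leukaemic cells is not excluded. A lower share together with another cause, and an effect of Pax5 dosage, were not tested and stay open.

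The arrays were also split in other ways into groups of the same sizes. For heterozygous leukaemias against B220+ cells the real split called 6336 genes, and another of 100 splits at most 750. For heterozygous precursors against wild type it called 832, and another of 35 splits at most 1. For precursors with both copies against wild type it called 5396, and another of 35 splits at most 11. For the stage difference of the heterozygous groups it called 6016, and another of 100 splits at most 213. Only the real split reached its count in each. Splits that mix the groups put a strong difference of any source into the spread, which lowers their counts. They therefore do not tell the source of a difference, and the count of 832 rests on single arrays. Between the oncogene-bearing precursors 10 splits are too few for a share under 0.05: the real split gave 5 genes and the highest other 770. The other splits that part all 3 same-numbered pairs gave 0 by limma. The split with 770 sets heterozygous precursors 1 and 3 with precursor 1 of both copies against the other 3 arrays, the narrowest of the 6 in range of values. That match was seen afterwards, and whether it accounts for the count was not tested.

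Single arrays stood apart from the rest of their group in 15 of 260 sets of values, where chance gives about 13. The sets share arrays and are not independent, so this near match does not make the outliers a matter of chance. Heterozygous leukaemia 7 was low in Sparc (9.65; others 11.19 to 12.21), Cxcl9 (7.45; 10.79 to 12.92) and Bgn (8.89; 10.54 to 11.50). Heterozygous leukaemia 6 was high in Fcmr (8.76; 5.90 to 7.03) and low in Igf2bp3 (7.80; 8.99 to 9.60). B220+ array 1 was low in the mean of PAX5-activated genes (11.27; 11.44 to 11.46), fatty acid oxidation (9.03; 9.21 to 9.28) and tumour suppressors (10.13; 10.28 to 10.33). It was also low in Klhl14 (9.88; 10.25 to 10.35), Pdk1 (7.65; 7.96 to 8.01) and Mcl1 (11.42; 11.67 to 11.71) and high in Fcnb (7.81; 6.76 to 6.99). This array had the highest neutrophil marker mean of its group (9.82, others 6.95 to 8.49). Its mean correlation with the group was the lowest (0.982, others 0.989 to 0.991). B220+ array 4 was high in cholesterol synthesis (8.91; 8.63 to 8.69), wild-type precursor 2 low in Spib (12.83; 12.979 to 12.997) and wild-type precursor 4 high in Kdm5d (5.28; 5.14 to 5.16).

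Effects that differed between stages by the interaction test numbered 138 genes for the Pax5 copy, 6016 for the heterozygous groups and 7463 for the groups with both copies. Those against wild type also hold the difference between the controls, B220+ cells and precursors. For the Pax5 copy the effects include Serpinb9d 5.36, Igf2bp3 3.08, Plch1 3.01, Il2ra 2.88, Mc5r -3.98 (-6.28 and -1.67 without leukaemia 1 or 2 with both copies), Prtn3 -3.60, Ms4a3 -3.01 and Padi4 -2.88, with list medians of -2.07 (-3.25 and -1.37 without precursor 1 or 3 with both copies) for neutrophil and 0.70 for NF-kB target genes. For the heterozygous groups they include Kcnma1 7.55, Jchain 7.18, Serpinb9d 5.38, Rnase12 5.30, Fcmr -5.95, Cpm -5.59, Ms4a1 -4.73 and Adck1 -4.56, with 1.14 for MYC target and 1.70 for cell cycle genes. For the groups with both copies they include Kcnma1 8.51, Emb 5.33, Jchain 5.31, Ctse 5.31, Cpm -6.32, Vpreb3 -5.67, Fcer2a -5.01 and Niban3 -4.93, with 1.32 and 2.19.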

How the results depend on the processing

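Cyclic loess, sex and residual-component covariates, the fit without arrays high in neutrophil markers, the block within 2 groups and the paired simulation were chosen after seeing the data; the planned surrogate-variable fit was not run. Of 4978 alternative values of 209 gene results, 4426 kept direction and side of the threshold, 514 lost and 9 gained the call, 13 moved and 16 reversed; of 998 for 47 list results the counts were 909, 82, 2, 0 and 5. Where a value changed, the cause was not tested, except that a minimum fold, fewer arrays or more probe sets change counts by construction. In the order of the report, counts with a minimum log2 change of 1 were 1518, 1766, 229, 92, 287, 3, 90 (Pax5 copy), 2024 and 2527. Median centring gave 12413, 8809 and 11138 for both leukaemias and the heterozygous stage difference; every probe set 9871 for heterozygous leukaemias and 1 between the oncogene-bearing precursors. Array weights gave 2281 for leukaemias with both copies, 83 between leukaemias, 5099 for heterozygous precursors, 79 between oncogene-bearing precursors, and 38, 9958 and 4044 for the stage differences (Pax5 copy, heterozygous, both copies). The residual component comes from the residuals of the group fit, so by construction it cannot move a fold change. All 209 gene results kept direction and call with it, which is no test of their direction. It gave 957, 1753, 17 and 396 between leukaemias, for heterozygous precursors, between oncogene-bearing precursors and for the Pax5 copy. All 24 arrays in 1 fit gave 1038, 275 and 2 for the first 3 of these, and the compared groups alone 85 between leukaemias and 0 between oncogene-bearing precursors. Sex in the fit gave 983 for precursors with both copies and 16 between oncogene-bearing precursors, and cyclic loess 3536 for the former. Without arrays high in neutrophil markers limma gave 0 (2479 at an unadjusted p under 0.05), 243 and 0 (2592) in the precursor comparisons, and 2994 and 4269 for the heterozygous and both-copy stage differences. The replicate block gave 2726, 106, 253 and 209 for leukaemias with both copies, between leukaemias, for heterozygous precursors and for the Pax5 copy, where groups share numbers alone; 15 of the 30 named genes of heterozygous precursors and 18 of the 25 between leukaemias lost the call. Between oncogene-bearing precursors, where the limit for pairing was passed though pairing is not established, the block gave 0 (2687 unadjusted), and 0 (1900) within those groups. It moved no other count by over 1.5 times. Lists past camera with an estimated correlation were 0 in all 6 comparisons; fry passed 6 between leukaemias, 1 for heterozygous precursors and 0 between oncogene-bearing precursors, where the dim filter, cyclic loess and leaving out neutrophil-high arrays each left 6 of 12 lists. With an array left out the counts ran 4816 to 6205, 2235 to 4755, 279 to 2137, 37 to 1063, 2331 to 6015 and 1 to 138, and 52 to 1381, 4741 to 6272 and 5739 to 7676 for the stage differences in that order, and lists between oncogene-bearing precursors 6 to 15. The precursor fold-change correlation was 0.634 at the lower end with split controls. Reversed with wild-type precursors as control were Cr2 0.10, Bub1b -0.70, Cenpf -0.31, Mcm3 -0.11 and the cell cycle list -0.38 in heterozygous leukaemias, and Fcer2a 0.48 and Cr2 0.31 in those with both copies. With B220+ cells as control Klrk1 0.038, Klrb1c 0.20, Fcer2a -4.92, Spib -0.065, PAX5-activated -0.054 and NK markers 0.060 reversed in heterozygous precursors, and Cdc25c 0.44, Mcm4 0.19, Bub1b 0.52 and the cell cycle list 0.50 in those with both copies. With sex in the fit Kdm5d was -0.045 and Xist 0.40. Without leukaemia 1 or 2 with both copies Abl1 was 0.61 or -0.69 in that group, and the glycolysis list between leukaemias -0.45 or 0.029. Dim genes carry less signal over background, and the dim filter changed no other count by over 1.5 times.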

Other observations

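The relations with the Pax5 level were planned; the lists below were fixed beforehand and chosen for description after their values were seen.

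In heterozygous leukaemias against B220+ cells (n = 7 and 5), STAT5 target genes, which BCR/ABL signalling is known to drive, went both ways: 6 of 18 rose and 6 fell (6 and 6 adjusted over the list alone). The list had a median of -0.073 and a mean of 0.32 and did not pass (camera adjusted p = 0.417, and adjusted p = 0.711 with an estimated correlation); with wild-type precursors as control the median was 0.26. The kinase Cdk6 rose (2.16 ± 0.20), while the survival gene Mcl1 (-1.17 ± 0.10) and the phosphatase Dusp5 (-1.53 ± 0.26) fell. Of 20 tumour suppressors of B cell leukaemia 11 fell and 2 rose (11 and 2 adjusted over the list alone), with Btg1 (-1.77 ± 0.16), Bach2 (-3.37 ± 0.33) and Spib (-2.72 ± 0.36) lower. The tumour suppressor list had a median of -0.46 (camera adjusted p = 0.0483, and adjusted p = 0.293 with an estimated correlation), and no longer passed without heterozygous leukaemia 1, 4 or 7 (camera adjusted p = 0.0526, 0.0633 and 0.0537) or B220+ array 3, 4 or 5 (0.0564, 0.071 and 0.0585). Nor did it pass after quantile normalization (camera adjusted p = 0.0591), with sex in the fit (0.07, median -0.30) or against wild-type precursors (0.0706). Markers of monocytes rose in the same arrays (median 2.94).

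Of 18 immediate early genes, known to respond to handling and sorting of cells, 11 fell and 1 rose in leukaemic marrow, for which the labels name no sort, against B220+ cells (12 and 1 adjusted over the list alone), with Fosb (-2.65 ± 0.20), Junb (-1.65 ± 0.13) and Jund (-2.06 ± 0.18) lower. The handling stress list had a median of -1.08 (camera adjusted p = 0.000827, and adjusted p = 0.249 with an estimated correlation), or -0.55 with wild-type precursors as control. Of 27 interferon response genes 8 rose and 1 fell (9 and 1 adjusted over the list alone). The interferon list had a median of 0.79 (camera adjusted p = 0.000654, and adjusted p = 0.532 with an estimated correlation).

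Heterozygous leukaemia 1 read as male by Xist (5.94) and had log2 levels of 6.58 for Eif2s3y, 5.84 for Kdm5d and 8.87 for Uty.

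Pax5 varied from 8.37 to 12.06 across the 7 heterozygous leukaemias, which allowed 6 relations to be tested with all 5040 permutations, two-sided. The hypothesis that list means vary with the Pax5 level was left undecided by each. Pearson's r with Pax5 was -0.218, -0.35, 0.518, 0.0737, 0.0419 and 0.000547 for PAX5-activated, PAX5-repressed, energy control, glycolysis, oxidative phosphorylation and MYC target genes, with exact permutation p = 0.629, 0.429, 0.235, 0.869, 0.937 and 0.999 and adjusted p = 0.999 for each. Spearman's rho was -0.0357, -0.286, 0.429, 0.0357, 0.321 and 0 in the same order, with exact permutation p = 0.963, 0.556, 0.354, 0.963, 0.498 and 1 and adjusted p = 1 for each. Without arrays 1 and 5, the farthest from the median Pax5 level, r was -0.379, -0.757, -0.00893, 0.125, 0.418 and 0.789. With 7 arrays a relation is not excluded, and a mean over the energy control genes can hide members that move opposite ways.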
